A study of Escherichia coli BW25113 with 6 samples.

How the data were processed

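Transcript levels were measured on 6 two-colour Agilent arrays of Escherichia coli. Each array set cDNA of the wild type BW25113, a K-12 laboratory strain, labelled with Cy3, against cDNA of a strain lacking gadE, hdeA or hdeD, labelled with Cy5, per the labels. Each strain had 2 arrays, described in the design text as biological replicates, and no array had the dyes exchanged. Cells grew at 37 °C in a minimal glycerol medium with 0.2% casamino acids to the middle of exponential growth. RNA was extracted with hot phenol, and 5 µg was labelled per sample, per the labels' protocols. The wild-type source names carry only the numbers 1 and 2 on the arrays of all 3 strains, so the same wild-type RNA may have been used on several arrays. A comparison with the wild type was tested as a log2 ratio against 0, which leaves out part of the wild type's own spread.

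The authors deposited Agilent Feature Extraction output for each array, with version 8.1 named per the submitters' processing notes. The deposited intensity columns hold the median pixel brightness of each spot and of its local background, and intensities after Feature Extraction's own background subtraction and dye normalization. The deposited log10 ratio column is the log10 of processed Cy5 over processed Cy3 intensity. The deposited series value table is also a log10 ratio, per its values: after matching by probe name it differed from the log10 ratio column by at most 0.00499 on any array, and each of its columns had a median of 0. Its scale, centring and direction were therefore settled by that match. Each deposited file held 1 row for each of 10751 probe names, and how repeated spots were reduced to 1 row was not given in the sources used here. No slide number or scan date was used here.

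The plan fixed before the data were examined called for mean spot intensities. The files analysed here gave median intensities, which were used in their place. Background was corrected with limma 3.58.1 in R 4.3.3 by normexp with an offset of 50 on the median spot and local background intensities, over all spots. Local backgrounds that Feature Extraction marked as background outliers were replaced by the median of the other spots of that array and channel, and spots whose local background exceeded 3 times the array's median were left out. This step was chosen after the data were seen. A total of 10 spots, 5 on each gadE-deficient array and none elsewhere, had such backgrounds, up to an intensity of 56973 against a median of 24. They were taken to distort the normexp correction of those arrays, which was not tested apart from the replacement of marked backgrounds. Results with the deposited backgrounds are given in the closing section. Ratios were then normalized within each array by loess, with control spots and outlier spots at weight 0, and outlier spots were left out. Positive values mean a higher level in the deficient strain.

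Of 10691 non-control probes, 4234 carried a K-12 locus tag, for 4209 genes, and only these entered the comparisons of genes. The other 6457 probes were designed on other E. coli strains and were tested apart. A probe was kept if it was well above background in either channel on at least 2 arrays. The mean of a gene's probes was used, and a gene needed values on at least 4 arrays and at least 1 per strain, which left 4183 genes, 4075 of them measured on all 6 arrays. Symbols were updated by locus tag through a RefSeq table of assembly ASM584v2, in which 4052 of the K-12 genes were found. This changed 442 probe symbols. The table was used only for names and gene order, since the files name no genome build.

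All 6 arrays were fitted together with limma (lmFit and eBayes, 3 residual degrees of freedom), so that the 3 strains shared the estimate of spread. Tests were two-sided and adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. The same fit gave the differences between strains, in which gene-specific dye effects common to the arrays cancel. The wild type cancels in full only where the same RNA was used for both strains. A total of 30 gene lists was fixed before the data were examined, and each was also tested with camera at a preset correlation of 0.01 and with an estimated one. Arrays with the same number deviated together from their strain means. The correlations of these deviations over genes were 0.117 for gadE and hdeA, 0.447 for gadE and hdeD and 0.58 for hdeA and hdeD, so the numbers were taken to pair the arrays. The pairing comes from the replicate numbers in the labels. The wild-type channels correlated at 0.989 to 0.994 between arrays of the same number and at 0.975 to 0.986 between arrays of different numbers. The fit with the number as a block was an alternative, and its values are given where they changed the call of a named gene or a set test, or moved a count by over 1.5 times. Against the wild type, the block takes the deviation shared by same-numbered arrays out of the spread. Its calls there do not allow for that deviation, and a gene of opposite sign on its arrays can be called.

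Genes were named by a rule fixed before the data were examined. It took the 3 targeted genes and the acid fitness island and GAD genes in every comparison, the 10 largest called rises and falls against the wild type with the same sign on both arrays, apart from the deleted gene, up to 4 called members of each list, and the 5 largest called differences each way between strains. Where fewer than 10 genes passed, up to 5 more in each direction were given as values only. Genes deleted in the parent strain served as a background check. Any other gene named was chosen after its values were seen. No saturated spot was found. The small number of arrays limits the precision. On simulated arrays with 100 genes changed 2-fold and 100 changed 4-fold in the gadE-deficient strain, over 4195 genes, 93% of the genes changed 2-fold and 99% of those changed 4-fold were called, and 4.95% of the calls were unchanged genes. The simulated noise was independent between genes and arrays, with even backgrounds, no outlier spots and no gene-specific dye effect or shared wild-type deviation. These rates may therefore be too favourable for the real arrays. Alternatives covered the background correction, the normalization, the filter on dim probes, the choice of probes, the model, the threshold and leaving out each array in turn.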

Results

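Transcript levels of 3 Escherichia coli strains, each deficient in gadE, hdeA or hdeD, were compared with their wild type in minimal glycerol medium at mid-exponential growth. GadE is the central activator of glutamate-dependent acid resistance, HdeA is a periplasmic chaperone that protects proteins at low pH, and HdeD is an inner membrane protein. The 3 genes are neighbours in the acid fitness island. Each strain had 2 arrays. Median Cy3 intensity, from the wild type, ranged from 1772 to 2666 per array and median Cy5 intensity, from the deficient strain, from 828 to 1541, over background medians of 24 to 25 and 31.5 to 32. Between 97.1% and 99.6% of K-12 probes were well above background in each channel. The SD over genes of the difference between the arrays of a strain was 0.50 for gadE, 0.47 for hdeA and 0.37 for hdeD on the log2 scale. The gadE-deficient arrays had 159 and 261 outlier spots, and the other arrays 27 to 80.

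Each targeted gene was low in its own strain. gadE (b3512) had log2 ratios of -3.64 and -3.59 on the gadE-deficient arrays, hdeA (b3510) -4.81 and -4.93 on the hdeA-deficient arrays, and hdeD (b3511) -2.10 and -2.36 on the hdeD-deficient arrays. The Cy5 signals left were 61 and 77.5 for gadE, 234.5 and 179 for hdeA, and 253.5 and 154 for hdeD, all still well above background. Where the probes lie within the deleted genes was not known here, so the residual signal is not a measure of transcript left. In the other strains gadE was between -0.55 and 0.46 on each array. Of 7 genes deleted in the parent strain, 6 were tested and none was called in any comparison. araD and rhaD gave Cy5 intensities of up to 1427 and 419, and lacZ up to 161.

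In the gadE-deficient strain, 9 of 14 measured genes of the island and the GAD system, gadE included, fell, and all 52 measured genes of flagella and chemotaxis rose. hdeA fell by 4.16 ± 0.15 (log2, SE, n = 2; 17.9-fold) and hdeB, the gene of its partner chaperone, fell by 3.90 ± 0.17 (14.9-fold). The glutamate decarboxylase genes gadB and gadA fell by 2.92 ± 0.14 and 2.21 ± 0.23, and gadC, which encodes the glutamate/GABA antiporter, fell by 2.40 ± 0.15. The gadA signal of the deficient strain was well above background on only 1 array, so the size of its fall is uncertain. For hdeA the Cy5 signals left were 226 and 462, against 234.5 and 179 in the hdeA-deficient strain. The 2 strains did not differ in hdeA by limma (0.70, adjusted p = 0.208). The size of its fall may thus be limited by the signal that its probe gives without the gene. fliC, encoding flagellin, rose by 4.77 ± 0.16 (27.3-fold) and cheA, the chemotaxis kinase gene, by 4.98 ± 0.18 (31.7-fold). In all, 251 genes were higher and 280 lower among 4183, and 277 of these 531 changed at least 2-fold. These counts rest on a background step chosen after the data were seen; with the deposited values of the outlying local backgrounds 81 were higher and 27 lower, 108 in all.

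Among the other island and GAD genes, gadX, a regulator of the system, fell by 2.06 ± 0.21 (adjusted p = 0.00217), hdeD by 1.42 ± 0.18 (adjusted p = 0.00511) and dctR by 0.78 ± 0.17 (adjusted p = 0.0339). hdeD did not pass by limma against the hdeD-deficient strain (0.81, adjusted p = 0.466), so the size of its fall may be limited likewise. The 5 not called were slp -0.21, gadW -0.35, mdtE 0.37, mdtF 0.30 and yhiD 1.44, the last with 0.44 and 2.44 on its arrays. Adjusted over the list alone, 9 fell and 2 rose. The set test gave an adjusted p of 0.000136 with the preset correlation and an adjusted p of 0.74 with an estimated correlation. With the deposited values of the outlying local backgrounds 4 of the 14 were called, and gadE at -1.16 (adjusted p = 0.0671), gadC at -0.96 (adjusted p = 0.0577), hdeD at -0.70 (adjusted p = 0.0546), gadA at -0.44 (adjusted p = 0.335) and dctR at -0.10 (adjusted p = 0.828) were not.

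**Figure D1:**
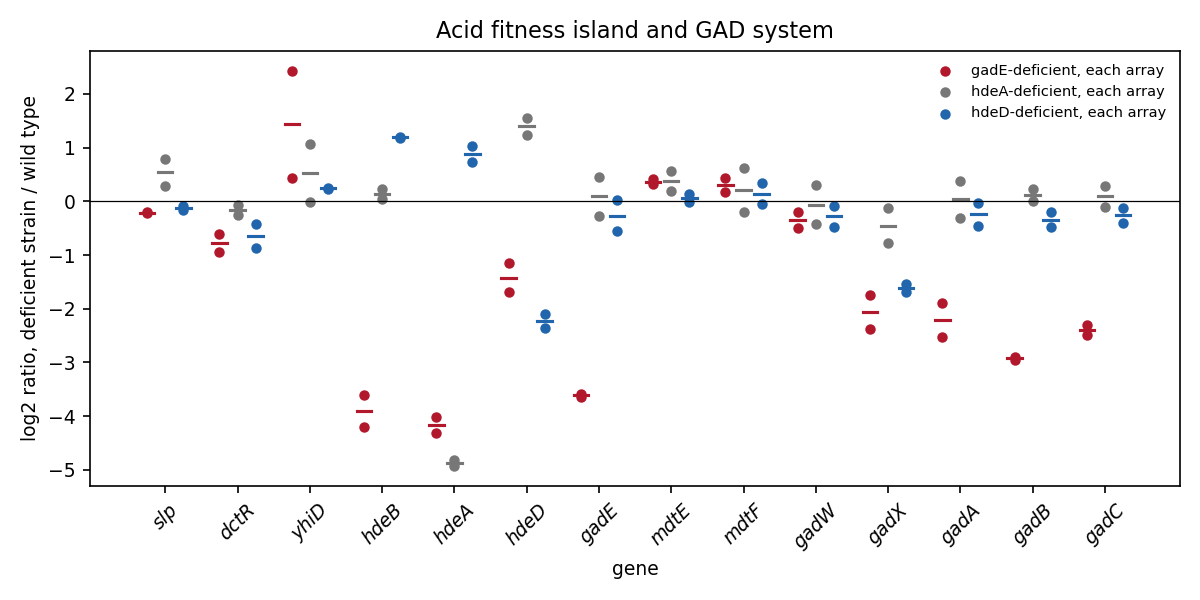
Log2 ratio of deficient strain over wild type (vertical axis) for 14 genes of the acid fitness island and GAD system (horizontal axis). Points are single arrays, 2 per strain, and bars their means. hdeB, hdeA, gadE, gadA, gadB, gadC and gadX lie below -1.5 on both gadE-deficient arrays, and hdeA and hdeB lie above 0.7 on both hdeD-deficient arrays.

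All 52 measured flagella and chemotaxis genes rose in the gadE-deficient strain, with a median of 2.66. The set test gave an adjusted p of 2.35e-66 with the preset correlation and an adjusted p of 0.244 with an estimated correlation. The 10 largest rises of the comparison were cheA and fliC with tsr, ycgR, cheR, cheW, cheY, motA, motB and tap, from 4.06 for tap to 4.98 for cheA, a range of 16.7 to 31.7-fold. tsr and tap encode chemoreceptors, motA and motB the motor's stator, and ycgR a c-di-GMP-responsive brake. Without either gadE-deficient array 49 of the 52 were called. Among 16 curli and type 1 fimbriae genes, 8 rose and 2 fell. fimA, the gene of the main pilus subunit, rose by 1.46 ± 0.17, fimI by 1.33 ± 0.17, csgC by 2.57 ± 0.14 and csgG by 1.39 ± 0.25. With the deposited values of the outlying backgrounds csgC was at 0.87 (adjusted p = 0.0601) and csgG at 1.22 (adjusted p = 0.0992), neither called, and csgG was at 0.89 (adjusted p = 0.118) without replicate 2. The falls were csgD at -0.71, the curli regulator gene, and csgE at -0.70. The set test gave an adjusted p of 0.00595 with the preset correlation and an adjusted p of 0.74 with an estimated correlation. Without replicate 1 or 2 of the strain 2 and 4 members were called, all of them higher.

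Of 33 genes of anaerobic metabolism, 12 fell, 2 rose and 19 were not called in the gadE-deficient strain (adjusted over the list alone, 17 fell and 2 rose). ansB, encoding periplasmic asparaginase, fell by 2.28 ± 0.39 and nrfB, of the formate-dependent nitrite reductase, by 2.14 ± 0.40. hyaA, of hydrogenase 1, rose by 2.12 ± 0.17. The other rise counted, torC at 2.64, was measured on replicate 2 alone, so its spread came only from the arrays of other strains and its call (adjusted p = 0.03) is not a test of replicates; it ended with the deposited outlying backgrounds (adjusted p = 0.112) and with replicate 1 left out (adjusted p = 0.0553). With the replicate block 20 fell and 2 rose. The set test gave an adjusted p of 0.000136 with the preset correlation and an adjusted p of 0.746 with an estimated correlation. Without replicate 1 of the strain 2 members were called, and without replicate 2, 8 were. The largest falls outside the lists were tdcD and tdcC, of threonine and serine catabolism and uptake, at -2.77 ± 0.56 and -2.65 ± 0.59, ygcO at -2.29 ± 0.31, and lrhA (b2289), a repressor gene of the flagellar master operon, at -2.45 ± 0.18 (5.46-fold, adjusted p = 0.000312). On the single arrays tdcD was at -3.535 and -1.996 and tdcC at -3.485 and -1.805.

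Amino acid genes moved in parts. In histidine biosynthesis 4 of 8 genes fell, from hisC at -0.56 to hisD at -0.78 (adjusted over the list alone, 7 fell). In branched-chain biosynthesis 2 of 13 fell, ilvC by 1.61 ± 0.19 and ilvM by 0.70 ± 0.13 (adjusted over the list alone, 7 fell; with the replicate block, 7 fell). In methionine and cysteine biosynthesis metE rose by 2.20 ± 0.24 and metC by 1.49 ± 0.22, while cysI fell by 1.57 ± 0.38 and cysH by 1.55 ± 0.38, with -2.44 and -0.71 and with -2.45 and -0.66 on the arrays, the other 19 of 23 passing neither way (adjusted over the list alone, 3 rose and 9 fell; with the replicate block, 4 rose and 5 fell). The calls of cysI and cysH ended without replicate 1 of the strain (adjusted p = 0.206 and 0.201) and when any 1 array of the other strains was left out. Purine and pyrimidine biosynthesis had 2 rises in 22, carA at 1.13 (1.51 and 0.75 on the arrays) and pyrI at 0.61, with 9 rises and 1 fall with the replicate block (adjusted over the list alone, 3 rose and 1 fell). Ribosomal proteins had 2 rises in 52, rpmF at 0.96 and rpmG at 0.74 (4 with the replicate block; adjusted over the list alone, 2). These lists apart from methionine and cysteine passed the set test with the preset correlation, at adjusted p values of 0.000363 to 0.0136, and none did with an estimated correlation (adjusted p of 0.74 to 0.746).

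Few members of the remaining lists were called in this strain. In the RpoS general stress list dps at 0.85, tktB at 0.80 and blc at 0.71 rose and cbpA at -0.68 fell, of 30. In iron acquisition fepA at 1.14 and sufB at 0.69 rose and exbB at -0.84 fell, of 32. Single rises were sodA at 1.08 of 16 oxidative stress genes, aceK at 1.16 (0.58 and 1.73 on the arrays) of 20 TCA cycle genes, nuoA at 0.49 of 21 respiratory chain genes, and astC at 0.81 (1.13 and 0.49 on the arrays) of 22 nitrogen assimilation genes. Single falls were glpA at -1.56 of 12 glycerol genes, evgA at -0.75 of 12 EvgA/YdeO genes, ibpA at -0.87 of 17 heat shock genes, pspC at -0.78 of 17 envelope stress genes, cspI at -0.68 of 10 cold shock genes, livG at -0.63 of 16 transport genes, and borD at -2.52 ± 0.33 of 9 PhoP/PhoQ genes. Arginine biosynthesis had carA higher and argA lower at -0.56, of 12. No member of the lists of other acid resistance systems (12 measured), maltose and galactitol (16), tryptophanase (2), tryptophan and aromatic biosynthesis (14), phosphate starvation (17) or SOS response (16) was called. Without replicate 2 of the strain aceK lost its call (adjusted p = 0.261), as astC did without replicate 1 (adjusted p = 0.206). With the deposited values of the outlying backgrounds blc, astC, ibpA, pspC, cspI, livG and argA lay between -0.41 and 0.31, and with median centring dps, tktB, blc and sufB lay between 0.32 and 0.47, none of them called. Adjusted over the list alone, 2 members fell in each of the EvgA/YdeO, glycerol and cold shock lists and 1 in the tryptophanase list, none passed in the nitrogen, respiratory chain and TCA cycle lists, and the counts of the others stayed as given. With the replicate block 8 rose and 3 fell in the RpoS list, 1 rose and 6 fell in the transport list, 5 fell in each of the glycerol and the maltose and galactitol lists, 2 rose and 4 fell in the iron list, 2 rose and 3 fell in the EvgA/YdeO list, 1 rose and 4 fell in each of the heat shock and envelope stress lists, 3 rose and 3 fell in the aromatic list, and 1 rose and 3 fell among other acid resistance systems; the nitrogen list then had 2 rises and also passed the set test (adjusted p = 0.0359, against 0.0515 without the block, where an estimated correlation gave an adjusted p = 0.746). The block also gave 1 rise and 3 falls in the respiratory chain list, 3 falls in cold shock, 2 rises and 1 fall in each of the phosphate and oxidative stress lists, 2 rises and 2 falls in arginine biosynthesis, 1 rise and 1 fall in each of the TCA cycle and PhoP/PhoQ lists, and 1 fall in each of the tryptophanase and SOS lists.

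The gadE-deficient strain had 1253 called genes with the replicate block, 426 higher and 827 lower, which include all 531. Of the 531, 12 rest on 1 array of the strain. The median log2 ratio of all genes on these arrays was -0.11, and loess on the K-12 probes alone, an alternative chosen after the data were seen, brought it to 0.00 with 281 genes higher and 165 lower; with median centring in place of loess 242 were higher and 1169 lower. Without replicate 1 or 2 of this strain 169 and 139 genes were called, and without replicate 1 or 2 of the hdeD-deficient strain 351 and 346.

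In the hdeA-deficient strain, 3 genes were called against the wild type without the replicate block and 366 with it. hdeA itself fell by 4.87 ± 0.15 (29.2-fold, adjusted p = 5.24e-05), gfcD rose by 1.98 ± 0.18 (3.95-fold, adjusted p = 0.0388) and fimD, the gene of the type 1 pilus usher, fell by 1.31 ± 0.13 (2.48-fold, adjusted p = 0.0388). These were the 3 called genes of 4183, while 913 had an unadjusted limma p under 0.05. gfcD was also at 2.02 and 1.92 in the gadE- and hdeD-deficient strains. A gene-specific dye effect or shared wild-type RNA would give the same, so its rise cannot be tied to the loss of hdeA. Beside hdeA, none of the 14 island and GAD genes passed. hdeD, which lies next to hdeA, was at 1.39 ± 0.18 (adjusted p = 0.0588, and 0.0298 with the replicate block), and hdeB was at 0.14 ± 0.17. gadE, gadA, gadB and gadC lay between 0.04 and 0.12, gadX was at -0.45, gadW at -0.06, slp at 0.54, dctR at -0.16, yhiD at 0.53, mdtE at 0.38 and mdtF at 0.21. None of the 52 flagella and chemotaxis genes was called, with a median of -0.19, and 4 were lower with the replicate block.

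The next largest values in this strain, none past the threshold, were ydjE at 2.07, yiaW at 1.89, yliL at 1.49, yncJ at 1.48 and yecN at 1.45, and on the lower side yeeR at -1.83, flu at -1.71, cspF at -1.34, ykfG at -1.33 and cspG at -1.29. cspF and cspG encode cold shock proteins and flu the autotransporter antigen 43. ydjE, yecN, yeeR, flu, cspF, ykfG and cspG passed with the replicate block, at adjusted p values of 0.0237 to 0.0357. Apart from the island list and the fimbriae list, no list had a called member. Adjusted over the list alone, 7 of 10 cold shock genes fell and 1 rose, 6 fimbriae and 6 branched-chain genes fell, 4 genes fell in each of the SOS, nitrogen and transport lists, with 1 rise in the last, and 2 heat shock genes rose. The island list had 1 rise and 1 fall, and the other lists at most 1 member so called. With the replicate block the members lower were 4 in cold shock, 6 in fimbriae, 5 in branched-chain, 4 in SOS, 5 in nitrogen and 5 in transport, and 3 RpoS and 3 methionine and cysteine genes were higher. The block also gave 3 lower purine and pyrimidine genes, 2 lower aromatic genes, 2 higher genes in each of the respiratory chain and heat shock lists, and 2 higher and 1 lower in each of the anaerobic and ribosomal lists. Other acid resistance, tryptophanase, envelope stress, transport and the island had 1 higher gene each, glycerol and oxidative stress 1 higher and 1 lower each, and maltose and galactitol, arginine, phosphate, iron and PhoP/PhoQ 1 lower each. Of the 30 lists 6 passed the set test with the preset correlation, with a lowest adjusted p of 0.00552 for methionine and cysteine biosynthesis, and none with an estimated correlation (lowest adjusted p of 0.766). The fimbriae, branched-chain and SOS lists no longer passed with the replicate block, at adjusted p values of 0.0671, 0.0737 and 0.0737, against 0.0344, 0.0496 and 0.0496. With the replicate block 366 genes were called, 114 higher and 252 lower, and with the deposited values of the outlying local backgrounds 16 were. With the strain's own arrays alone 117 were called, and with median centring in place of loess 357, 20 higher and 337 lower. gfcD and fimD lost their calls without either array of any strain, and 1 to 2 genes were then called.

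In the hdeD-deficient strain, the flagella and chemotaxis genes all rose, hdeA and hdeB rose, and gadX fell. fliC rose by 5.91 ± 0.16 (60.2-fold) and cheA by 5.61 ± 0.18 (49-fold). hdeB rose by 1.19 ± 0.17 (2.28-fold, adjusted p = 0.0138) and hdeA by 0.89 ± 0.15 (1.85-fold, adjusted p = 0.0282), each on both arrays. gadX fell by 1.61 ± 0.21 (3.05-fold, adjusted p = 0.00891). In all, 84 genes were higher and 18 lower, and 88 of these 102 changed at least 2-fold.

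Of the 14 island and GAD genes, 2 rose and 2 fell, hdeD and gadX, and the others were not called: gadE -0.26, gadA -0.24, gadB -0.34, gadC -0.26, gadW -0.28, slp -0.12, mdtE 0.07, mdtF 0.14, yhiD 0.24 and dctR -0.65 (adjusted p = 0.138, and 0.0269 with the replicate block). Adjusted over the list alone, 2 rose and 3 fell. The rises of hdeA and hdeB ended with Agilent's processed signals (adjusted p = 0.0664 and 0.0642) and with median centring (0.0706 and 0.0524), with values of 0.60 to 1.16. They and the fall of gadX also ended without replicate 1 or 2 of this strain (gadX adjusted p = 0.0814 and 0.115), when 1 of the 14 was called. The hdeA call further ended without either array of the hdeA-deficient strain (adjusted p = 0.0533 and 0.0549).

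All 52 flagella and chemotaxis genes rose in this strain too, with a median of 3.16. The set test gave an adjusted p of 1.64e-105 with the preset correlation and an adjusted p of 0.121 with an estimated correlation, and 50 were called without either array of the strain. The 10 largest rises were fliC, cheA, tsr, ycgR, cheR, cheW, cheY, motB, tap and pdeH, from 4.81 for pdeH, a c-di-GMP phosphodiesterase gene, to fliC. Among the curli and fimbriae genes 4 of 16 rose: csgC by 3.26 ± 0.14, fimA by 1.49 ± 0.17, fimI by 1.19 ± 0.17 and fimF by 0.76 ± 0.13 (adjusted over the list alone, 6 rose). Without replicate 1 of the strain 1 of these was called. That list's set test gave an adjusted p of 0.000278 with the preset correlation and an adjusted p of 0.527 with an estimated correlation. Besides hdeD itself, the 10 largest falls were borD at -2.90 ± 0.33, lrhA at -2.06 ± 0.18 (4.16-fold, adjusted p = 0.000742), ygcO at -1.84, ilvC at -1.72, yddB at -1.64, gadX, pfkB at -1.28, which encodes the minor phosphofructokinase, uspC at -1.18, lldR at -1.15, the lactate operon's regulator gene, and qseB at -1.09.

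**Figure D2:**
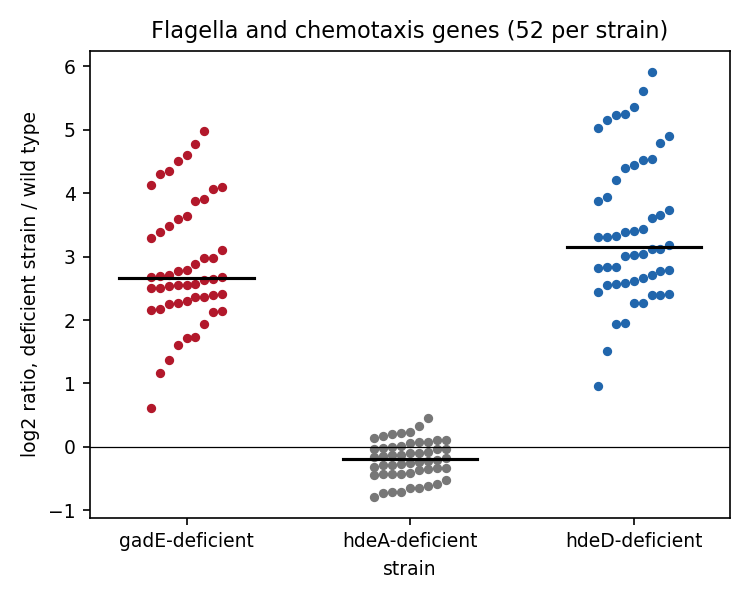
Log2 ratio of deficient strain over wild type (vertical axis) for each of 52 flagella and chemotaxis genes in the 3 strains (horizontal axis). Each point is 1 gene's mean over 2 arrays and the line is the median. All points of the gadE- and hdeD-deficient strains lie above 0, with medians of 2.66 and 3.16, and those of the hdeA-deficient strain spread around a median of -0.19.

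Small groups of amino acid genes were lower in the hdeD-deficient strain. ilvC and leuA, at -0.83 ± 0.15, fell among 13 branched-chain biosynthesis genes (adjusted over the list alone, 8 fell; with the replicate block, 6), livG and livF, of branched-chain amino acid uptake, fell by 0.96 ± 0.14 and 0.69 ± 0.12 among 16 transport genes (with the replicate block, 7 fell and 1 rose), and trpD fell by 0.74 ± 0.13 among 14 aromatic genes (with the replicate block, 2 fell). No histidine gene of 8 was called, while 6 were lower with the replicate block and 7 were lower adjusted over the list alone. dps rose by 0.99 ± 0.14 among 30 RpoS genes (3 rose with the replicate block), rpmF by 0.95 ± 0.15 among 52 ribosomal genes (2 rose with the replicate block), and sulA fell by 0.74 ± 0.12 among 16 SOS genes. Besides flagella and fimbriae, the histidine, branched-chain, transport, RpoS, iron and SOS lists passed the set test with the preset correlation, at adjusted p values of 3.84e-05 to 0.0461, and none did with an estimated correlation (adjusted p of 0.233 to 0.823); SOS no longer passed with the replicate block (adjusted p = 0.0897). borD was the called member of 9 PhoP/PhoQ genes, where 2 fell with the replicate block, and the lists not named had no call. Adjusted over the list alone, 4 transport genes fell and 1 rose, 2 cold shock genes fell and 1 rose, 1 oxidative stress gene rose and 1 fell, and each other list not given so far had its count as stated. In all 333 genes were called with the replicate block, 143 higher and 190 lower, among them 5 lower anaerobic genes. The lower ones included 2 nitrogen and 2 TCA cycle genes and 1 gene in each of the other acid resistance, maltose and galactitol, heat shock, cold shock, phosphate and oxidative stress lists. The higher ones included 2 purine and pyrimidine genes and 1 gene in each of the respiratory chain, methionine and cysteine, iron and oxidative stress lists. With median centring 83 were higher and 130 lower.

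Flagella and chemotaxis genes were higher in the gadE- and in the hdeD-deficient strain than in the hdeA-deficient strain. Against the hdeA-deficient strain, fliC was higher by 5.10 ± 0.22 in the gadE-deficient strain and by 6.24 ± 0.22 in the hdeD-deficient strain. In all 94 genes differed between gadE and hdeA, 70 higher and 24 lower in the gadE-deficient strain, of which 49 of the higher ones were flagella and chemotaxis genes. Between hdeD and hdeA 79 differed, 74 higher and 5 lower in the hdeD-deficient strain, and 50 of the higher ones were flagella and chemotaxis genes. Flagella and chemotaxis genes were a smaller part of the calls with the replicate block, 51 of 344 between gadE and hdeA, and 51 of 94 between hdeD and hdeA. The list's set tests gave adjusted p values of 9.01e-83 and 7.01e-176 with the preset correlation, and adjusted p values of 0.175 and 0.054 with an estimated correlation.

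Island genes separated the strains as well. The largest values lower in the gadE- than in the hdeA-deficient strain were hdeB at -4.04 ± 0.24, gadE at -3.70 ± 0.31, gadB at -3.04 ± 0.19, borD at -2.82 ± 0.47 and hdeD at -2.82 ± 0.25. gadC at -2.49 and gadA at -2.25 were also lower, and gadX at -1.61 was not called (adjusted p = 0.0533, and 0.015 with the replicate block). Curli and fimbriae genes were higher in 8 of 16 and anaerobic genes lower in 2 of 33, while with the replicate block 19 anaerobic genes were lower and 1 higher (adjusted over the list alone, 12 and 1). That block also gave 7 higher purine and pyrimidine genes and 4 lower glycerol genes, where none was called without it. It further gave 3 higher genes in each of the nitrogen and aromatic lists and 1 in each of arginine and cold shock, 2 lower in each of other acid resistance, RpoS, respiratory chain, heat shock and iron, and 1 lower in each of tryptophanase, transport and oxidative stress. In the same comparison cheA at 5.16, tsr at 4.84, cheR at 4.93 and tap at 4.71 joined fliC as the largest higher values. From gadE to hdeD 6 genes differed: hdeB at -5.09 ± 0.24, hdeA at -5.05 ± 0.21, gadE at -3.35 ± 0.31, gadB at -2.59 ± 0.19 and gadC at -2.14 ± 0.22 were lower in the gadE-deficient strain, and rspA at 3.11 ± 0.35 was higher. No flagella and chemotaxis gene of 52 was called between these strains by limma, with a median of -0.58 (with the deposited values of the outlying local backgrounds 17 were lower, and with the replicate block 1), although 400 of all genes had an unadjusted limma p under 0.05. The list was lower by its set test, with an adjusted p of 2.03e-15 with the preset correlation and an adjusted p of 0.572 with an estimated correlation. The largest values lower in the hdeD- than in the hdeA-deficient strain were hdeD at -3.62, borD at -3.19, lrhA at -2.12 ± 0.25, yddB at -1.99 and pfkB at -1.51. The largest higher ones were fliC, cheA at 5.79, hdeA at 5.75, cheR at 5.68 and tsr at 5.61. With the replicate block 344 genes differed between gadE and hdeA, 117 higher and 227 lower, and 54 between gadE and hdeD, 7 higher and 47 lower, among them 11 lower and 1 higher anaerobic genes, 1 higher aromatic gene, and 1 lower gene in each of the respiratory chain, tryptophanase and iron lists. Between hdeD and hdeA the block gave 1 lower gene in each of the other acid resistance and anaerobic lists. Without either gadE-deficient array, or without replicate 2 of the hdeD-deficient strain, 2 genes differed between gadE and hdeD, and with the deposited values of the outlying local backgrounds 29 did.

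**Figure D3:**
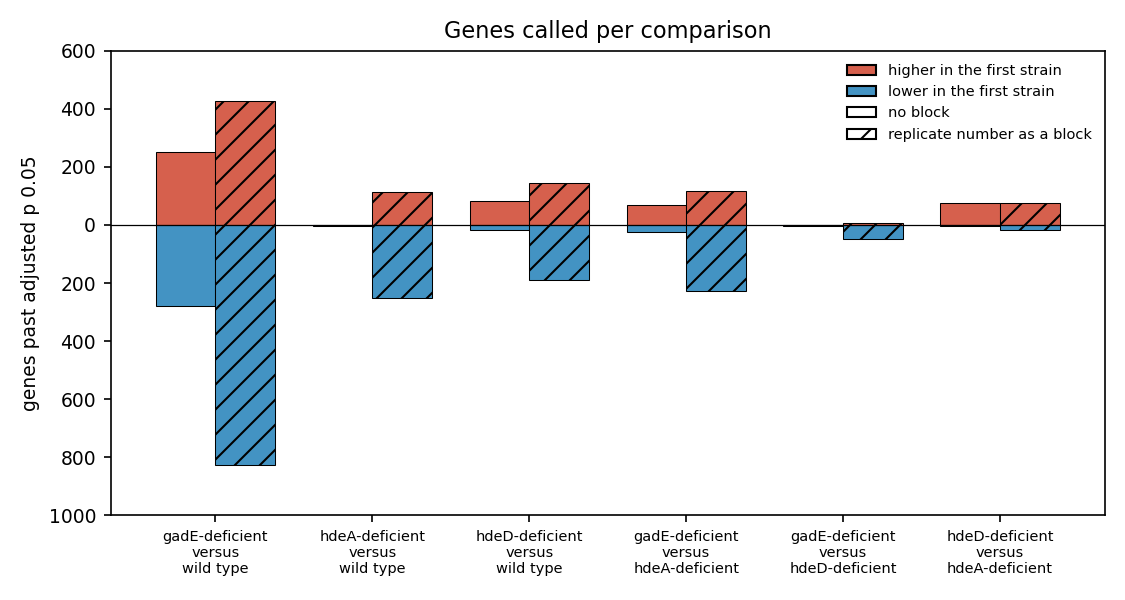
Number of genes past an adjusted p of 0.05 (vertical axis, higher above 0 and lower below 0) in the 6 comparisons (horizontal axis), without a block (plain bars) and with the replicate number as a block (hatched bars). The gadE-deficient strain has the most calls against the wild type, 531 without and 1253 with the block. The hdeA-deficient strain has the fewest against the wild type without the block, 3, and the hdeD-deficient strain with it, 333.

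Across 4075 genes, the log2 ratios of the gadE- and hdeD-deficient strains correlated at r = 0.757 (Spearman 0.612), against 0.35 in 100 simulations of unchanged strains sharing wild-type RNA. Genes are not independent replicates. The covariance was 0.278 against a simulated 0.0177. Both strains had 77 genes higher in common, against 5.04 for independent lists, and 13 lower, against 1.2, while 2 were called in opposite directions, and part of the excess may come from the shared wild type. All 52 flagella and chemotaxis genes were called higher in both strains, and no correlation without them is given here. For gadE and hdeA r was 0.364 against a simulated 0.349, and for hdeA and hdeD it was 0.358 against 0.348, with covariances of 0.0877 and 0.073 against a simulated 0.0176 for each. The Spearman correlations of these pairs were 0.411 and 0.675. By rank, therefore, hdeA and hdeD were closer than gadE and hdeD. Every pair was simulated with the same shared wild-type variance. The deviations of same-numbered arrays, however, correlated at 0.117 for gadE and hdeA and at 0.58 for hdeA and hdeD. A near match of r for a single pair therefore does not show where its correlation comes from.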

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

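All tests on hdeA and hdeB, and the test on dye effects and shared wild-type RNA for the flagella genes, were chosen only after the results were seen. The tests on flhDC and on the genes beside lrhA were recorded as fixed before their values were seen. However, nuoA, which lies beside lrhA, was already a named gene at 0.49 in the gadE-deficient strain. For that gene and strain the outcome was therefore partly known.

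Values between strains are those of the first strain named minus the second. The effect of a deficiency differed between strains, by the test of the difference itself, for 94 genes between gadE and hdeA, 79 between hdeD and hdeA and 6 between gadE and hdeD. Between gadE and hdeA these include fliC at 5.10, cheA at 5.16, cheR at 4.93, tsr at 4.84 and tap at 4.71, and on the lower side hdeB at -4.04, gadB at -3.04, borD at -2.82, hdeD at -2.82, gadC at -2.49 and gadA at -2.25. Between hdeD and hdeA they include fliC at 6.24, cheA at 5.79, cheR at 5.68, tsr at 5.61, borD at -3.19, lrhA at -2.12, yddB at -1.99 and pfkB at -1.51. Between gadE and hdeD they include hdeB at -5.09, hdeA at -5.05, gadB at -2.59, gadC at -2.14 and rspA at 3.11. They also include targeted genes in their own strain, gadE at -3.70 and -3.35, hdeD at -3.62 and hdeA at 5.75, and 49 and 50 flagella and chemotaxis genes in the comparisons with hdeA.

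The rise of the flagella and chemotaxis genes was shared by the gadE- and hdeD-deficient strains and absent from the calls in the hdeA-deficient strain. A gene-specific dye effect, or wild-type RNA shared by all 3 strains, would cancel between strains. The smaller of the median differences from the hdeA-deficient strain was 2.90, which argues against both for this list. The list's medians were known when the difference was chosen as a test, so it adds nothing to them. Wild-type RNA shared by the gadE- and hdeD-deficient strains alone would not cancel and was not tested. A candidate explanation is the lower lrhA, whose product represses flhDC: flhD and flhC differed from the hdeA-deficient strain by 1.09 and 1.36 in the gadE-deficient strain, a mean of 1.22, and by 1.44 and 1.71 in the hdeD-deficient strain, although any other route to higher flhDC would give the same. Since flhDC is the flagellar master operon, its rise was likely once that of the flagella genes was known. The test therefore does not single out lrhA. A chromosomal change that also silences the genes on either side of lrhA is argued against, since the lowest difference of nuoA and alaA from the hdeA-deficient strain was -0.21. A second mutation in lrhA or elsewhere in these strains, and an effect of losing gadE or hdeD itself, were not separated by these data.

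In the hdeD-deficient strain hdeA and hdeB, next to the deleted gene, rose and no other island gene was called higher. Higher GadE activity was looked for in gadA, gadB and gadC, whose mean log2 ratio there was -0.28. Their values had been seen before, and gadX, a regulator of the system, fell by 1.61 in the same strain. The test therefore cannot decide on GadE activity. The other 8 measured genes from slp to gadX had a median of -0.19, so these values held no rise of all genes near the deletion. They too had been seen before this test was chosen. A gene-specific dye effect or shared wild-type RNA cannot be told apart from a biological change, because hdeB differed from the hdeA-deficient strain by 1.05 without passing the threshold (adjusted p = 0.185). An effect of the deletion on its immediate neighbours, and a biological role of HdeD, remain open and untested.

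Probes designed on other E. coli strains were tested apart from the K-12 genes and also gave calls. Against the wild type these were 385 of 4125 in the gadE-deficient strain, 344 higher and 41 lower, 12 in the hdeD-deficient strain, 11 higher and 1 lower, and 0 in the hdeA-deficient strain. Between strains they were 12 for gadE and hdeA, 10 for hdeD and hdeA and 0 for gadE and hdeD. These calls were not assigned to K-12 genes here. The loess fit used both kinds of probes, and the median of the K-12 genes in the gadE-deficient strain was -0.11. Whether the excess of higher calls in that strain comes from the normalization was not tested.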

How the results depend on the processing

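The alternatives that kept the deposited backgrounds, fitted loess on K-12 probes alone, or added same-symbol probes of other designs were chosen only after the data were seen; the others were fixed before the data were examined.

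Keeping the deposited values of the outlying local backgrounds gave 108 called genes in the gadE-deficient strain in place of 531 (81 higher and 27 lower), 16 in the hdeA-deficient strain and 29 between gadE and hdeD. With no background correction at all, an alternative fixed beforehand, the gadE-deficient strain had 535, of which 521 were among the 531. Of 129 called named gene comparisons 48 lost their call with the deposited backgrounds. The counts thus depend on how outlying local backgrounds were treated.

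With median centring in place of loess 1411, 357 and 213 genes were called in the gadE-, hdeA- and hdeD-deficient strains, with a median of all genes of -0.32, -0.24 and -0.24. The split for gadE, 251 higher and 280 lower, became 242 and 1169, 281 and 165 with loess on K-12 probes alone, 233 and 393 with Agilent's log ratio and 234 and 394 with the series value table. For the hdeA-deficient strain 1 gene was called with Agilent's processed signals, with its log ratio, with the series value table and with loess on K-12 probes alone, 5 with an intensity trend, 117 from its own arrays alone and 15 by 2-fold on both arrays with no test. For the gadE-deficient strain 277 passed with a 2-fold minimum and 201 were 2-fold on both arrays with no test. The cause was not tested.

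With the replicate block 1253, 366 and 333 genes were called in the gadE-, hdeA- and hdeD-deficient strains, 344 between gadE and hdeA and 54 between gadE and hdeD. The counts against the wild type leave out the spread shared by same-numbered arrays. It ended no call of a named gene and changed no other call of a named gene than those given above, and no other list count moved by over 1.5 times. Between strains, the set tests of glycerol genes for gadE and hdeA (adjusted p = 0.0328) and of aromatic and phosphate genes for gadE and hdeD (0.0125 and 0.0257) passed with it at the preset correlation. Without the block these set tests gave adjusted p values of 0.0763, 0.0589 and 0.0589, and of 0.572 to 0.696 with an estimated correlation. Those of methionine and cysteine and of iron genes for hdeD and hdeA (0.0742 and 0.0541) no longer passed with the block, against 0.043 and 0.0426 without it. Against the mean of the other strains 53 genes were called for gadE and 90 for hdeA, and 5 values reversed: dps -0.20, cspI 0.25, nuoA -0.010 and livG 0.33 in the gadE-deficient strain, and gadB 1.06 in the hdeD-deficient strain. That setting compares with strains that hold changes of their own. Single arrays of different numbers gave a mean correlation of 0.624 for gadE and hdeD and 0.184 for hdeA and hdeD, where means of both arrays gave 0.757 and 0.358. Single arrays of the same number gave 0.765 and 0.671 for gadE and hdeD and 0.417 and 0.345 for hdeA and hdeD. For gadE and hdeA they gave 0.423 and 0.144, and arrays of different numbers -0.0775 and 0.531, so that pair's sign depends on the arrays.

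Leaving out each array in turn gave 139 to 585 called genes for gadE, 1 to 2 for hdeA and 70 to 105 for hdeD against the wild type, 67 to 89 between gadE and hdeA, 2 to 6 between gadE and hdeD and 67 to 76 between hdeD and hdeA. A strain's lone array is then assumed to vary like the others. Without replicate 1 or 2 of the gadE-deficient strain 53 and 51 of the called named gene comparisons lost their call, and without replicate 1 or 2 of the hdeD-deficient strain 42 and 41. Of the 129, 62 lost their call against the mean of the other strains and 21 with only the strain's own arrays. Neither of these settings covered the differences between single strains. A further 14 lost it with loess on K-12 probes alone, 12 with Agilent's processed signals and 10 with median centring, each counted apart. It was lost by 5 with a normexp offset of 10, 3 with an intensity trend and 1 with no background correction. With same-symbol probes of other designs added, fliC rose by 2.44 in the gadE-deficient strain and by 3.06 in the hdeD-deficient strain, and cspI was at -0.060. Aquantile after loess leaves log ratios as they are, and so tests nothing. A block for slide or scan date was not run. At least 97.1% of K-12 probes were well above background on each array, which does not show a transcript to be present. Of the 7 genes deleted in the parent strain, 4 or 5 were also well above background in Cy5 on each array. How many genes are limited by signals near background was therefore not settled.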

Other observations

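Genes in this part were chosen after their values were seen. In the gadE-deficient strain, several operons of anaerobic respiration with few or no members in the fixed lists had called falls. They were picked by their values, and no set test was run on them. All 7 measured nap genes, of the periplasmic nitrate reductase, fell, from -1.31 to -2.04, each on both arrays. Of 8 hyb genes, of hydrogenase 2, 6 fell, with a median of -1.42, and of 7 genes named hyp, most of them of hydrogenase maturation, 4 fell, with hypE at -1.91. Of 8 ccm genes, of cytochrome c maturation, 4 fell, and of 6 nik genes, of nickel uptake, 4 fell and 1 rose, with nikA at -1.62. nrdD, of the anaerobic ribonucleotide reductase, fell by 1.78. The arrays differed in size, with napA at -2.53 and -1.46 and hypE at -2.48 and -1.34. With the deposited values of the outlying local backgrounds only 27 of all genes were called lower in this strain, so these calls may depend on that step. The nap, hyb, hyp, ccm and nik genes had no call in the hdeA- and hdeD-deficient strains without the replicate block. With it 6 nap, 7 hyb, 3 ccm and 2 hyp genes were lower in the hdeD-deficient strain. In the hdeA-deficient strain 2 nap, 3 hyb, 1 ccm and 1 hyp gene were, and no nik gene was lower in either. These blocked calls leave out the spread shared by same-numbered arrays. The hyp gene so called in the hdeA-deficient strain, hypE, was at -1.12 and 0.11 on its arrays (limma adjusted p = 0.0458 with the block). A limit to 1 strain was therefore not shown, and the blocked calls do not settle it. Against the hdeA-deficient strain no nap, hyb, hyp or ccm gene was lower past the threshold, while with the replicate block 7, 5, 5 and 5 were, so for these genes the difference between the strains rests on the pairing of arrays. Of the nik genes 1 was lower without the block, nikA by 2.42 (adjusted p = 0.0162), and 4 were with it.

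Several genes outside the flagella list rose in both the gadE- and hdeD-deficient strains. flxA was at 3.52 and 4.28, yecR at 2.75 and 3.42, ymdA at 2.85 and 3.25, rdcA at 2.75 and 3.67, rcsA at 1.26 and 1.26 and gfcD at 2.02 and 1.92. gfcD was also the rise called in the hdeA-deficient strain, at 1.98, so it stood at a similar value against the wild type in each of the 3 strains. For gfcD a gene-specific dye effect or shared wild-type RNA cannot be told apart from a change in the strains. ygcN fell by 1.97 in the gadE-deficient strain and was at -1.70 in the hdeD-deficient strain (adjusted p = 0.0509, and 0.000746 with the replicate block).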
